A study of Zea mays with 4 samples.

How the data were processed

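RNA was extracted from endosperm at 12 days after pollination, with 30 endosperms per replicate, from B73 and emf1 (mn8) kernels, giving 4 libraries in 2 groups of 2. Per the labels' protocols, total RNA was isolated with TRIzol, treated with DNase I, made into mRNA-seq libraries and sequenced on an Illumina NovaSeq instrument. Per the submitters' processing notes, the genome build was B73 RefGen v4. The aligner, the annotation release and whether strand was used are not given in the sources used here. Groups and replicate numbers came from the sample titles.

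The authors deposited 1 transcript table per library. Each lists the same 136579 transcripts of 45261 genes with a coordinate, an FPKM value (fragments per kilobase of transcript per 1000000 fragments), lower and upper bounds on it, an isoform fraction and a coverage. Read counts and TPM were not among these columns. Every number that follows was computed from the deposited FPKM, its bounds and the coverage. Gene FPKM was the sum over a gene's transcripts, and TPM was FPKM divided by its library sum and multiplied by 1000000, so the choice made before the data were examined, which took TPM as deposited, was met with a TPM recomputed from FPKM. Because FPKM is not a count, count models were not the main test. For genes with 1 transcript the upper bound was taken to lie 2 times FPKM over the root of the fragment number above the value, which gives an estimate of that number. With a tolerance of 0.05, between 70.9% and 71.9% of the values under 50 fragments came out whole. Sequencing depth was taken from the slope of fragments per FPKM on transcript length, over transcripts of at least 500 bases.

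Each library's TPM was divided by the median, over 9316 genes with a TPM of at least 10 in all 4 libraries, of its ratio to the gene's geometric mean. The factors were 0.893 and 0.892 for B73 and 1.138 and 1.103 for emf1, a shift of 0.33 on the log2 scale. Genes with a TPM of at least 1 in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3 (linear model on the group, empirical Bayes with a variance trend) on log2(scaled TPM + 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on the log2 scale therefore include a pseudocount of 1 and understate changes of weak genes, and counts of genes past 2-fold, 4-fold or 8-fold use this scale. Fold values given for single genes or sums are ratios of mean scaled TPM, which can be larger. With 2 against 2 libraries an exact permutation test cannot go below 0.333, so p-values rest on the model, and the depth of each library limits the precision of weak and short features. Bounds and fragment numbers cover counting error only. Libraries were simulated from the real gene levels, and every gene of a level was given that level's pooled replicate spread. In these libraries 200 of 19909 tested genes were changed. The same code recovered 6% of genes changed 1.5-fold, 30% changed 2-fold and 98% changed 4-fold or 8-fold, with 5 calls among unchanged genes. As genes of a level shared the same spread, this does not show how the test does where spreads differ between genes. The simulated changes were few, and as many went up as down. They therefore test neither the scaling step nor recovery where many genes change. On real gene positions a planted window was found and random changes gave 0 windows, with smaller shares of genes changed than were called in the data.

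Windows of 10 Mb with at least 10 tested genes were compared with the rest of the genome by Fisher's exact test. Pairs of neighbouring genes and gene structure were tested by 100000 permutations within deciles of mean level, for pairs also within chromosomes. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for these steps, and matplotlib 3.10.9 for the plots.

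The rule for named genes was fixed before the data were examined. It asked for annotated genes with the largest changes and, where no table pairs names with identifiers, for the 2 identifiers with the largest rise and the 2 with the largest fall among called genes with a mean scaled TPM of at least 5 in a group and no overlap between groups. The reference table given (assembly Zm-B73-REFERENCE-NAM-5.0) matched 0 of 43487 nuclear identifiers and 153 of 154 microRNA loci. The planned comparisons of ZmEMF1a itself, of the Polycomb, zein, starch, transcription factor and other gene lists, and of markers of other kernel tissues therefore could not be made, and these genes are not analysed here. The labels could not be checked against the mutated gene for the same reason.

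Alternatives fixed before the data were examined were no scaling factor, quantile normalization, FPKM in place of TPM, pseudocounts of 0.1 and 5, no level filter, a TPM minimum of 5, no variance trend, robust variance estimates, the replicate number as a block, each library left out in turn, windows of 5 and 20 Mb, and a log2 change of at least 1 in place of the call. Alternatives chosen after seeing the data were nuclear genes only, leaving out the 10 most abundant genes, voom weights on fragments estimated from coverage, genes with a longest transcript of at least 500 bases, and an 8-fold criterion for windows.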

Results

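Gene expression in maize endosperm, the starch- and protein-storing tissue of the kernel, was measured by RNA-seq at 12 days after pollination in kernels labelled B73 and in the emf1 mutant, which the labels also call mn8. The mutant carries a defect in ZmEMF1a. EMF1 proteins work with the Polycomb group, chromatin regulators that keep genes silent through the histone marks H2Aub and H3K27me3. The comparison asks which transcripts change in endosperm when ZmEMF1a is impaired. Each group held 2 libraries, each made from 30 endosperms, and the labels place mutant and B73 endosperms on shared F2 ears. Taken at its word, this makes the B73 group non-mutant siblings on those ears, but its name is that of the inbred line. The labels do not settle which holds. They also differ on the number of independent ears behind the replicates, which is 2 in the design text and 3 in the extraction protocol. Depth was estimated from the error bounds in the deposited values at 24800000 and 16700000 fragments for B73 replicates 1 and 2, and at 19900000 and 27700000 for emf1 replicates 1 and 2. Every library was quantified over the 45261 annotated genes. Replicates lay close together. The median absolute difference between libraries on the log2 scale was 0.12 within B73 and 0.10 within emf1, against 0.50 to 0.51 for pairs across the groups. Across genes, which are not independent replicates, Pearson's r was 0.989 within B73, 0.987 within emf1 and 0.898 to 0.904 across the groups. The variance between replicates was 2.53 times that of counting noise in B73 and 6.88 times in emf1, so neither pair looked like 1 library deposited more than once.

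The emf1 endosperm transcriptome differed from B73 over much of the genome. Of 20103 genes tested, 8808 (43.8%) were raised and 4256 (21.2%) were lowered in emf1 at an adjusted p under 0.05 (limma moderated test on log2(scaled TPM + 1), two-sided, Benjamini-Hochberg, n = 2 per group). Large changes were mostly rises. Among called genes, on the log2(scaled TPM + 1) scale, 3690 were raised and 825 lowered at least 2-fold, 760 were raised and 130 lowered at least 4-fold, and 193 were raised and 29 lowered at least 8-fold. With a pseudocount of 5 the counts at 2-fold were 1415 raised and 438 lowered. They were 2042 and 1563 after quantile normalization, and 5296 and 455 without a scaling factor. Restricted to nuclear genes with standard gene models, 128 were raised and 28 lowered at least 8-fold. The median size of the log2 change was 0.87 among raised genes and 0.58 among lowered genes. In 83.0% of tested genes the 2 emf1 libraries lay both above or both below the 2 B73 libraries, where chance gives 33.3%. The split between directions depended on how libraries were scaled. Raised genes made up 67.4% of calls in the main comparison, 85.2% without a scaling factor (12511 raised, 2173 lowered) and 47.4% after quantile normalization (5801 raised, 6446 lowered), and the median log2 change of all tested genes was 0.23, 0.52 and -0.04 in these 3 cases.

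Among genes with a mean scaled TPM of at least 5 in a group and no overlap between groups, the steepest fall in log2(scaled TPM + 1) was that of Zm00001d030855, a single-exon gene at chromosome 1 positions 163526102 to 163526827 (B73 RefGen_v4). Its scaled TPM was 1203 ± 20.5 in B73 and 38.7 ± 3.40 in emf1 (SD, n = 2 each), which is 31.1-fold lower (log2 change -4.92, SE 0.064). The next steepest was Zm00001d048810, a single-exon gene at chromosome 4 positions 5880093 to 5880632, which fell 22.6-fold from 322.6 ± 21.7 to 14.3 ± 1.21 (log2 change -4.41, SE 0.078, limma adjusted p = 1.93e-06). By the same rule the steepest rises belonged to ENSRNA049479461 on chromosome 6 (92505181 to 92505266) and ENSRNA049476322 on chromosome 7 (8518187 to 8518274), short features from Ensembl's series for non-coding RNA. Both were listed at 0 in both B73 libraries. The scaled TPM was 2021 and 2885 for the first and 1653 and 1152 for the second in emf1 replicates 1 and 2. The deposited bounds place only 2 to 4 fragments behind each of these values, and each lower bound is 0. Whether these features rose, and by how much, is therefore poorly determined. The files pair no names with nuclear gene identifiers, so other nuclear genes are described by position, and these were chosen after their values were seen.

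Most of the most abundant endosperm transcripts fell. The gene with the highest level over the 4 libraries, a single-exon gene at chromosome 7 positions 123982344 to 123983015, had a scaled TPM of 70242 ± 999.7 in B73 and 15514 ± 976.8 in emf1 (SD, n = 2 each), 4.53-fold lower. Of the 100 most abundant genes by mean TPM of the 4 libraries, 85 were lowered, 9 were raised and 6 did not pass the test. At least 2-fold falls were seen in 37. The RNA was correspondingly less concentrated. The 10 most abundant genes of each library held 16.4% ± 0.23 of TPM in B73 and 6.5% ± 0.18 in emf1, and the top 100 held 34.6% ± 0.35 and 19.7% ± 0.36 (SD, n = 2 each). Reaching 50% of TPM took 370.5 ± 6.36 genes in B73 and 1022.5 ± 41.7 in emf1. These shares need no scaling between libraries, whereas the calls do. Without a scaling factor 69 of the 100 were lowered and 19 raised. Their median log2 change was then -0.36, against -0.69 in the main comparison. Quantile normalization, which forces the same distribution on each library, left 38 of the 100 lowered and 34 raised and gave the most abundant gene a log2 change of 0.00 (adjusted p = 1). Not all abundant transcripts fell. A gene of 6 exons at chromosome 6 positions 127318662 to 127321705 rose 3.78-fold from 1863 ± 27.8 to 7043 ± 10.2, and a gene of 4 exons at chromosome 7 positions 177324035 to 177325796 rose 4.41-fold from 1159 ± 38.0 to 5103 ± 62.3 (limma adjusted p = 2.19e-06 for each).

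**Figure D1:**
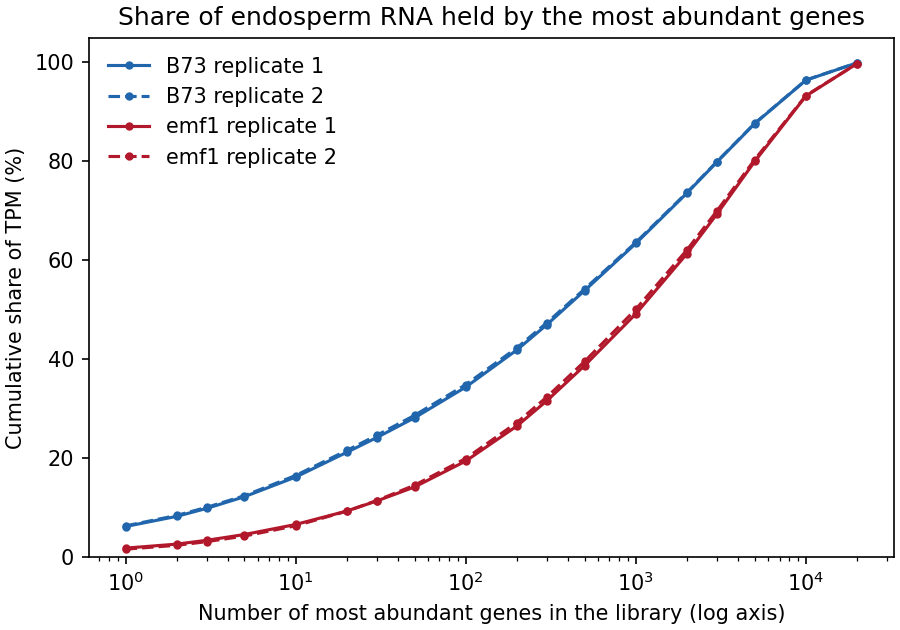
Cumulative share of TPM (y axis, percent) against the number of most abundant genes counted (x axis, log scale) in each of the 4 libraries. Both emf1 curves run below both B73 curves, with 19.4% and 19.9% of TPM in the top 100 genes against 34.4% and 34.9%.

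Weakly expressed genes moved the other way. Among tested genes with a mean scaled TPM under 2, 50.3% were raised and 7.9% lowered. Raised genes then declined and lowered genes increased with level, to 8.8% raised and 85.7% lowered above 1000, and the median log2 change went from 0.60 to -0.73. Without a scaling factor the same ends were 0.77 and -0.40, while quantile normalization left 0.12 and -0.02. The shares describe tested genes only, since weak genes can pass the level filter through the group where they are higher. That filter used TPM before scaling, so emf1 libraries met it at a lower scaled TPM than B73 libraries. With no filter, 28486 genes were tested, of which 8742 were raised and 3971 lowered. Genes with a TPM of at least 1 numbered 17914 and 17875 in B73 and 20179 and 20211 in emf1. At a scaled TPM of 1, 1451 nuclear genes lay at or above the level in both emf1 libraries and below it in both B73 libraries, of which 1355 were called raised. The reverse held for 245 genes, of which 186 were called lowered. Requiring at least 5 in the higher group gave 143 and 15 genes. Without a scaling factor the counts at 1 were 1792 and 175. Quantile normalization gave 708 and 688 genes. It gives each library the same number of genes at or above a level, so near-equal counts follow from the method and do not test the asymmetry. Leaving out 1 library, which relaxes the criterion, took the 245 to 411 and 408 without B73 replicates 1 and 2, and to 346 and 368 without emf1 replicates 1 and 2, against 1771 to 1821 genes in the other direction.

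**Figure D2:**
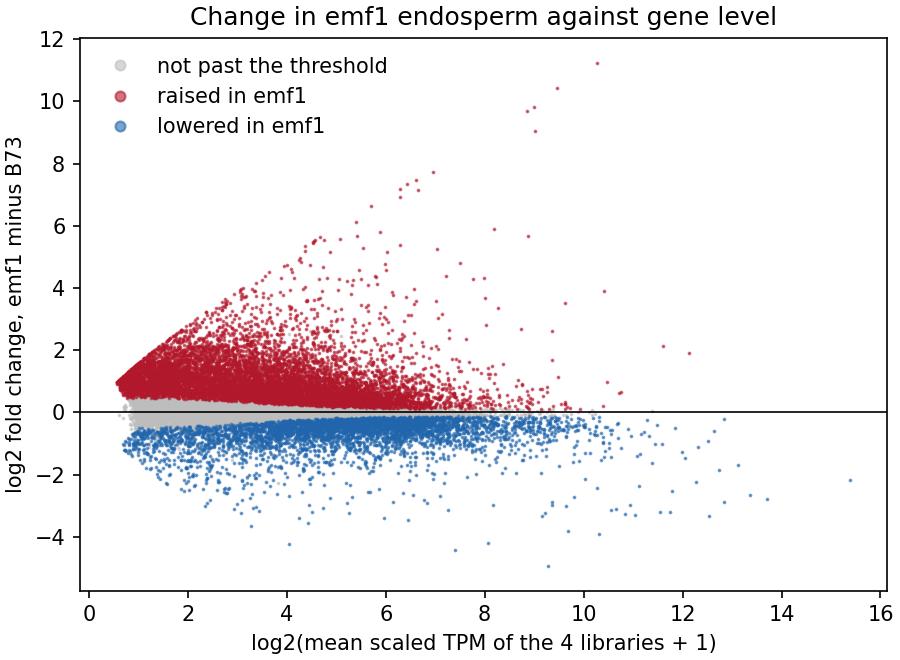
Log2 fold change of each of the 20103 tested genes (y axis, emf1 minus B73) against its level (x axis, log2 of the mean scaled TPM of the 4 libraries plus 1), with the 8808 raised genes in red, the 4256 lowered in blue and the others in grey. Rises dominate at low levels and falls at high levels. This pattern also held without a scaling factor. It is largely lost under quantile normalization, which forces the same distribution on each library.

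A run of similar gene models near the start of chromosome 4 accounted for many of the steepest falls. Between positions 5846538 and 6359146, 15 of 28 tested genes were lowered at least 2-fold. All 15 lay on the plus strand, 13 had a single exon, and the longest transcripts measured 399 to 804 bases. Their summed scaled TPM was 27770 ± 936 in B73 and 3416 ± 91.2 in emf1 (SD, n = 2 each), 8.13-fold lower, with falls of 4.41-fold to 22.6-fold for single genes and a highest limma adjusted p of 0.000209. The run includes Zm00001d048810. Whether these genes are close copies that share reads was not tested, so the division of the sum among them is uncertain. This region was singled out after its values were seen. At least 14 of the 15 were lowered under each alternative tried, including those without a factor and with quantile normalization.

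Several of the steepest rises sat together on chromosome 7. From 12903625 to 16746406, 7 of 38 tested genes were raised at least 8-fold and 11 at least 2-fold. The 7 had 2 to 3 exons and longest transcripts of 348 to 1904 bases, and their summed scaled TPM went from 9.23 ± 0.682 to 373.1 ± 11.5 (SD, n = 2 each), 40.4-fold higher, with a highest limma adjusted p of 6.24e-05. They include the 3 largest rises among nuclear genes by log2 change with a pseudocount of 1. The gene at 13728526 to 13729624 rose from 1.06 ± 0.225 to 114.8 ± 4.67, that at 13590380 to 13590963 from 0.649 ± 0.141 to 82.7 ± 10.7, and that at 16745486 to 16746406 from 0.414 ± 0.370 to 65.3 ± 5.92. All 7 were called under each scaling. Without either emf1 replicate 3 were called, since the others then reached the level filter in too few libraries to be tested.

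**Figure D3:**
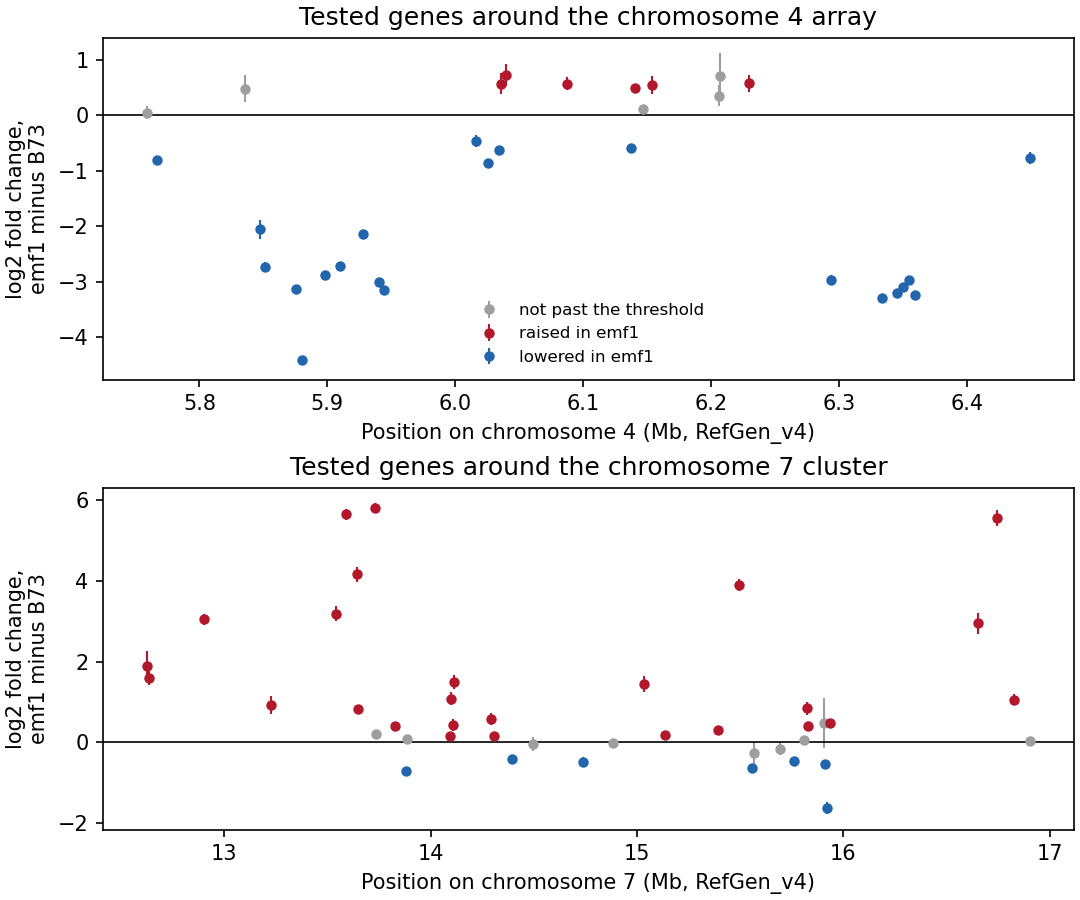
Log2 fold change (y axis, emf1 minus B73, bars show the SE from limma) of tested genes by position (x axis, Mb) on chromosome 4 around the 15 lowered genes (top) and on chromosome 7 around the 7 genes raised at least 8-fold (bottom). Red points were raised, blue lowered, and grey did not pass the test.

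Changed genes lay on all 10 chromosomes. The share of tested genes raised ran from 41.0% on chromosome 4 to 46.8% on chromosome 10, and the share lowered from 18.3% on chromosome 10 to 23.2% on chromosome 4. Of 215 windows of 10 Mb, 0 differed from the rest of the genome in raised genes and 0 in lowered genes (Fisher's exact test, two-sided, Benjamini-Hochberg), while 18 and 11 had an unadjusted p under 0.05. With a log2 change of at least 1 in place of the call, 1 window stood out in each direction. In chromosome 6 at 10000001 to 20000000, 26 of 45 genes (57.8%) were raised against 18.4% elsewhere (Fisher's exact test, adjusted p = 1.04e-06). Of these 45 genes, 29 are ENSRNA features at 12748054 to 14508688. Among the 60 ENSRNA features annotated there, 16 have the same length, and another 9 are nearly the same length as each other. They may therefore be repeated copies, whereas the test takes genes as independent. The window is thus no evidence for a region of separately raised genes. Whether the features share sequence or reads was not tested. In chromosome 4 at 1 to 10000000, 19 of 130 (14.6%) were lowered against 4.1% (adjusted p = 0.000373), and 15 of these 19 belong to the run described above. Under a criterion of at least 8-fold, taken up after the chromosome 7 genes had been seen, chromosome 10 at 80000001 to 90000000 also stood out, with 6 of 86 genes raised (7.0% against 0.9%, adjusted p = 0.0113).

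Non-coding and organellar features also differed, unevenly between the emf1 libraries. Of 143 tested ENSRNA features, 98 were raised and 3 lowered, and on chromosome 6 at 12748054 to 14508688 this held for 25 raised and 0 lowered of 29, which made up most raised genes of the window above. Fragments on ENSRNA features were estimated at 186.2 and 172.8 per 1000000 in B73 replicates 1 and 2, and at 833.2 and 2497 in emf1 replicates 1 and 2. Of 16 tested mitochondrial features, 13 were raised and 0 lowered, with 9.94 and 8.06 fragments per 1000000 in B73 against 42.1 and 128.9 in emf1. Plastid features behaved otherwise, at 31.1 and 34.5 in B73 and 11.02 and 36.7 in emf1. Of 13 tested, 4 were lowered and 0 raised, a count that ran from 0 to 9 when single libraries were left out. The ENSRNA count was 58 without emf1 replicate 1, 45 without emf1 replicate 2 and 65 with robust variance estimates, and the mitochondrial count was 5 and 2 without emf1 replicates 1 and 2. Restricting tests to longest transcripts of at least 500 bases left 22 ENSRNA and 8 mitochondrial features raised, and a TPM minimum of 5 left 6 mitochondrial features. For the chromosome 6 features the counts were 16 without B73 replicate 2, 16 and 15 without emf1 replicates 1 and 2, and 9 with robust estimates.

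**Figure D4:**
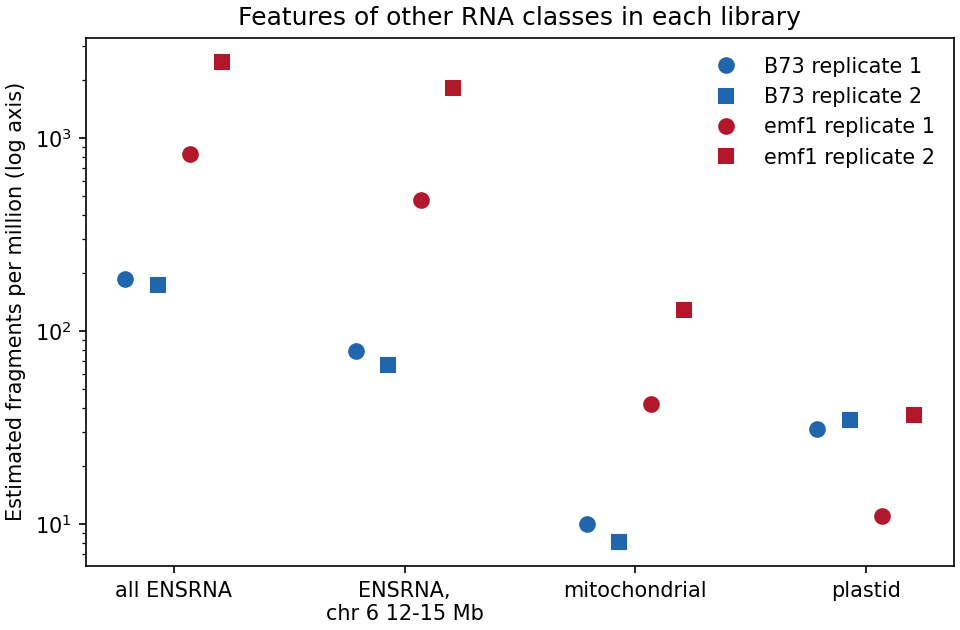
Estimated fragments per 1000000 (y axis, log scale) on ENSRNA features, on the ENSRNA features of chromosome 6, on mitochondrial features and on plastid features, 1 point per library. For all but the plastid features both emf1 points lie above both B73 points, and emf1 replicate 2 lies above replicate 1 in each class.

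MicroRNA loci were the one class whose identifiers matched names in the reference. Of 154 loci, 3 reached the level for testing. The locus zma-MIR167g, at chromosome 3 positions 119394584 to 119394826, fell 3.85-fold from a scaled TPM of 83.0 ± 20.7 in B73 to 21.5 ± 0.229 in emf1 (SD, n = 2 each; log2 change -1.88, SE 0.159, limma adjusted p = 0.000222). Plant miR167 is known to target auxin response factor transcripts. The mRNA-seq values here come from fragments over the annotated locus, and the mature microRNA was not measured. These values rested on 51 and 66 fragments in B73 and 20 in each emf1 library, and the locus shares its position and strand with 1 other annotated feature. The sum of both was 102.5 ± 6.78 in B73 and 27.0 ± 7.54 in emf1, 3.79-fold lower. The neighbouring zma-MIR167a, at 119392621 to 119392810, was also called lowered (log2 change -2.90, SE 0.612, limma adjusted p = 0.00739), with at most 3 fragments in any library and 1 other annotated feature at its position. Its log2 change ran from -5.97 with a pseudocount of 0.1 to -1.28 with a pseudocount of 5, so its size is poorly determined. For zma-MIR159a the scaled TPM was 1.34 ± 1.89 in B73 and 1.46 ± 2.06 in emf1 (limma adjusted p = 0.965).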

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

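The counts of raised and lowered genes stayed within 1.5 times the main count under most alternatives; the exceptions follow. Quantile normalization gave 5801 raised and 6446 lowered genes, with 2042 raised and 1563 lowered at least 2-fold. Leaving out the scaling factor gave 2173 lowered genes, 455 of them at least 2-fold. Quantile normalization forces the same distribution on each library. Without the factor, the shift of 0.33 between the groups on the log2 scale stays in the values. The median log2 change of all tested genes then went from 0.23 to 0.52. A pseudocount of 5 gave 1415 and 438 genes changed at least 2-fold, since it shrinks changes of weak genes, and voom on estimated fragments, chosen after seeing the data, gave 1336 lowered at least 2-fold (the cause was not tested). Leaving out single libraries gave 6116 to 8030 raised and 3597 to 3718 lowered genes, the lone sample of a group being assumed to vary like the other group. All 4 named identifiers stayed past the threshold wherever they were tested, the 2 ENSRNA identifiers in 14 alternatives each. For these 2 the alternatives reuse the same few fragments, so passing them does not settle whether the features rose. Windows past the threshold for raised genes went from 0 to 1 with 5 Mb and to 1 with a log2 change of at least 1, both an excess on chromosome 6. With 20 Mb the 1 window was a deficit on chromosome 2 (120000001 to 140000000, 17.0% against 43.9%). The 8-fold criterion, taken up after the chromosome 7 genes had been seen and so no independent test of them, gave 3 windows, on chromosomes 6, 7 and 10, and for lowered genes either fold criterion gave 1. With the replicate number as a block, 8726 genes were raised and 4215 lowered. Across tested genes, the difference between replicates 1 and 2 in B73 had a correlation of -0.027 with that in emf1. The numbers thus gave no sign of pairing, though 2 libraries per group make this a weak check. The alternative without zein genes was not run, nor were any for ZmEMF1a, the gene lists and the tissue markers, as their identifiers could not be matched. Depth limits short features: the 2 named ENSRNA identifiers rest on 2 to 4 fragments in each emf1 library.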

Other observations

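The tests of the plastid sums below were chosen after the result was seen, as were the comparisons of gene structure and transcript usage; the other tests were fixed before their results were seen. Genes lowered at least 2-fold were often intronless. Among 816 such nuclear genes, 220 (27.0%) had a single exon, where permutation within levels gave 14.4% (two-sided permutation p = 2e-05, the smallest the permutations can give), and their median longest transcript was 1280 bases against 1938 in other tested genes. Genes raised at least 2-fold had a single exon in 18.9% of 3580 cases against 18.1% in permutations (two-sided permutation p = 0.179). Transcript usage was compared within and between groups. Of 8751 nuclear genes with more than 1 transcript and a mean scaled TPM of at least 5 in both groups, the leading transcript differed between B73 replicates in 14.8% and between emf1 replicates in 12.5%, and between libraries of different groups in 14.7% to 15.7%. A switch shared by both replicates of each group was seen in 242 genes (2.8%), for which no chance value was computed.

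More genes were detected in emf1, with 20179 and 20211 at a TPM of at least 1 against 17914 and 17875 in B73. Unequal depth is argued against: after thinning each library to the same number of estimated fragments, the lowest emf1 library still had 1778 more genes with at least 10 fragments than the highest B73 library, where libraries of 1 group differed by at most 86. Room freed by the fall of abundant genes was tested by raising every B73 TPM by the 1.26-fold ratio of the factors. This left emf1 ahead by 1678 genes, so room of that size does not account for the whole gap. The ratio is a median over genes with a TPM of at least 10, which include abundant genes that fell. It may therefore understate the room freed, and a larger effect of this kind is not excluded. RNA from other kernel tissues stays open, as does a delay in development, because marker genes could not be matched and neither was tested.

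Neighbouring genes tended to rise together. Among adjacent tested nuclear genes, 804 pairs were both raised at least 2-fold, against 651.3 in permutations within chromosome and level. Reads shared by overlapping genes or tandem copies could give such pairs. Pairs on opposite strands that do not overlap, 390 against 307.04, were 1.27 times the permuted number and above the highest of 100000 permutations (375). Overlap and same-strand copies therefore do not account for the whole excess. Copies in opposite orientation could still share reads, and likeness of sequence was not examined, so shared reads are not excluded. For genes lowered together the picture differed. Opposite-strand pairs numbered 13 against 15.96, a ratio of 0.81, while same-strand pairs numbered 41 against 16.8, so tandem copies, with shared reads or shared control, may make up the excess there. Shared chromatin control of raised neighbours is a hypothesis that expression data alone do not test.

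ENSRNA and mitochondrial features stood higher in emf1 than in B73 and higher in emf1 replicate 2 than in replicate 1. Carry-over of RNA without poly(A) tails may account for the gap between the 2 emf1 libraries: the plastid sum, a further class mostly without such tails, was 3.33 times higher in replicate 2, which the explanation needs. That ratio reflects a low replicate 1, with plastid sums of 16.1 and 53.5 in emf1 replicates 1 and 2 against 45.7 and 56.7 in B73. Replicate 1 stood above B73 in ENSRNA and mitochondrial features but below it in plastid features, so the ratio is weak support. For the gap between groups the plastid sums overlapped, with an emf1 mean 0.679 times that of B73, so carry-over and a change caused by the genotype cannot be told apart with 2 libraries per group. The calls for these classes are best read with that in mind.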
